A study of Escherichia coli BL21(DE3) with 10 samples.

How the data were processed

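RNA and DNA were measured by sequencing in E. coli BL21(DE3) cells that expressed 1 of 2 SPARTA complexes, or in material co-purified with these complexes. SPARTA is a defence system of bacteria built on a short Argonaute protein and a partner protein with a TIR domain. The complex called MapSPARTA in the labels is named Map here, and the complex called CrtSPARTA is named Crt. Per the labels, cells grew at 37 °C in LB, and the complexes carried a his-MBP tag and were purified on Ni-NTA and amylose resin. The 10 samples form 9 groups. There are 8 RNA groups of 1 library each: total or complex-associated, long or small RNA, for each complex. No pull-down without a complex is among the samples. Associated RNA therefore cannot be told apart from RNA carried over in the purification. The last group is the DNA that came with the Map complex, with 2 samples that share 1 column of counts.

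The submitters listed Trim Galore, cutadapt 0.6.6, HISAT2 2.1.0 and featureCounts 2.0.1, with the version of cutadapt as they gave it. The deposited tables hold expected counts (fractional read counts per annotated feature), neither scaled for depth nor for length. The strand setting of the counting is not given in the sources used here. Each table has 4169 rows, of which 5 belong to the expression plasmid: LacI, the complex, the F1 origin, KanR and the pBR322 origin. These are the row names as given, while the labels name the vector pColADuet-1, so it is open whether the origin rows describe the origins of this vector. The complex row is 4188 bp long in the Map tables and 4086 bp in the Crt tables. It was read as the complex of each table's title, although a summary label in the Crt tables names the Map complex. Values were rounded to whole counts. A deposited overview of read and alignment numbers (unit other: a summary written by the authors) was used only for alignment rates.

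Rows were sorted into classes before any ratio was taken. The 7 rows of 16S and 7 rows of 23S rRNA were found by length, and their sum differed by 0 counts from the rRNA total deposited by the authors in each of the 9 tables. 5S rRNA is 1 row that stands for 8 copies. The 94 rows without a symbol that have tRNA length (70 to 95 bp) were set apart as tRNA-length rows, since the tables do not name tRNAs. The remaining 4055 chromosomal genes were compared. Of 2737 rows with a symbol, 2690 matched the gene table of the K-12 strain, and 1427 rows carry only a locus identifier. The lacI row and the plasmid LacI row stand for the same gene, and the MBP tag is encoded by malE, so that reads could be assigned to either place. No sequence was used here to test this, and neither chromosomal row is read as the chromosomal gene alone.

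For each comparison of 2 libraries, the log2 ratio of counts divided by library size was taken per gene, with a prior count of 0.5 and the sum of the compared genes as the library size. Genes with at least 100 counts over both libraries entered. The 95% interval of each ratio is the exact conditional binomial interval, and the interval of each share is the exact Clopper-Pearson interval. There was 1 library per group, so no ratio could be checked against replicates and no p-values were computed. All intervals cover counting error only. The reads carry no molecular identifiers, so copies of 1 molecule count as separate reads. The counts were also fractional before rounding, so the intervals hold only approximately. A threshold of 4-fold was used to count genes. For a gene with 0 counts in a library, a floor of 3 counts in that library gives the lower bound of its fold.

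The lacI row held up to 86.3% of the compared counts in a library and therefore moved the ratio of every other gene. Folds and log2 values per gene are for this reason given relative to the median gene of the comparison, except where a share of counts is named. The median itself is given once per comparison. This centring was chosen after the share of lacI had been seen. A value relative to the median gene is the same under any library scaling, apart from the prior count. Where the sign of a list's median before centring depends on the scaling, this is stated.

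The groups, the comparisons, 23 gene lists with 511 genes (419 of them in the tables) and the rule for naming genes were fixed before the data were examined. The rule took the 8 highest and 8 lowest genes of each associated-against-total comparison, the 5 highest and 5 lowest of each Map-against-Crt comparison, the 5 genes with most counts per library, the vector-related and lac genes, and the highest and lowest member of each list. Of these, genes known only by an identifier are mostly left out of the text. List members named beyond this rule were chosen after their values were seen. The median of each list with at least 5 measured genes was placed among 10000 random lists of the same size matched for expression. The random lists were drawn gene by gene, so list members that share a transcript count as separate genes. This percentile describes these libraries and is not a test.

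The alternatives were TMM factors, median-of-ratios factors, all assigned counts as the library size, count minimums of 10 and 1000, a prior of 5, thinning of the deeper library, shares without rRNA, Spearman in place of Pearson correlation, and correlations without vector-related, small RNA and ribosomal protein genes. A library size without lacI and malE, and median-of-ratios factors between the complexes, were added after the data had been seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 (for TMM factors only) were used. The methods were tested on simulated data made from these libraries with known changes. In the simulated Map small RNA comparison, 95.4% of the true values of 3644 genes lay in their 95% interval, and in the Map long RNA comparison 95.8% of 554 genes. No gene that was left unchanged in the simulation was called at 4-fold relative to the median gene. Apart from the changed genes, both simulated libraries had the same expected shares, with counting error only. These results largely follow from that design, so the simulation checks the calculation alone. It holds no spread between libraries and no difference in the lacI share.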

Results

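The data comprise 8 RNA libraries and a pooled DNA column from E. coli BL21(DE3) that expressed the Map or the Crt complex. The total long RNA libraries held 19318284 (Map) and 26899871 (Crt) assigned counts, and the complex-associated long RNA libraries 18698561 and 25938974. The total small RNA libraries held 12024516 (Map) and 13477060 (Crt), and the associated small RNA libraries 28027775 and 10439250. A count of 0 in the shallowest RNA library allows a share of up to 2.87e-05%. The DNA column held 894 counts. The authors' overview gives alignment rates of 98.2% (Map) and 98.3% (Crt) for associated long RNA, and of 72.8% (Map associated), 67.6% (Map total), 62.6% (Crt associated) and 52.9% (Crt total) for small RNA. The descriptions of the 4 associated RNA samples name the other complex than their titles do, and the titles were followed.

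16S and 23S rRNA, the RNA of the ribosomal subunits, filled the long RNA libraries, and reads of the expression plasmid filled the small RNA libraries. In long RNA, 16S rRNA held 42.7% of the counts in Map total, 50.2% in Map associated, 37.3% in Crt total and 48.8% in Crt associated RNA, and 23S rRNA held 54.4%, 46.1%, 61.1% and 50.4% in the same order. In both complexes the ratio of these rRNAs was thus shifted towards 16S in the associated library. In small RNA, plasmid rows held 54.5% (Map total), 48.4% (Map associated), 63.9% (Crt total) and 46.4% (Crt associated). The lacI and malE rows, which may hold reads of the plasmid, are not part of these shares. 5S rRNA, the small RNA of the large subunit, held a larger share of associated than of total small RNA with both complexes. It went from 0.604% to 2.39% with Map, a 3.95-fold difference (95% interval 3.92 to 3.98), and from 0.352% to 13.5% with Crt, a 38.4-fold difference (38.1 to 38.8). With Crt, 16S and 23S rRNA also held larger shares of associated small RNA, by 7.31-fold and 4.95-fold. With Map, 16S held a 1.10-fold smaller and 23S a 1.45-fold larger share. The Crt folds rest on low shares in Crt total small RNA, 0.643% and 1.43%, against 9.66% and 10.5% in Map total. Crt associated small RNA held less of both than Map associated, 4.70% against 8.81% for 16S and 7.06% against 15.2% for 23S. In long RNA, 5S rRNA held a 2.58-fold larger share of associated RNA with Map and a 3.02-fold smaller share with Crt. The chromosomal genes outside rRNA, lacI, malE, the small RNA list and tRNA-length rows moved in the same directions as 5S rRNA. Together their share of associated small RNA was 2.48-fold larger with Map and 3.65-fold larger with Crt. In long RNA it was 2.24-fold larger with Map and 1.44-fold smaller with Crt. The tRNA-length rows held 3.89% of Map total and 1.05% of Map associated small RNA, and 0.605% and 0.576% with Crt.

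**Figure D1:**
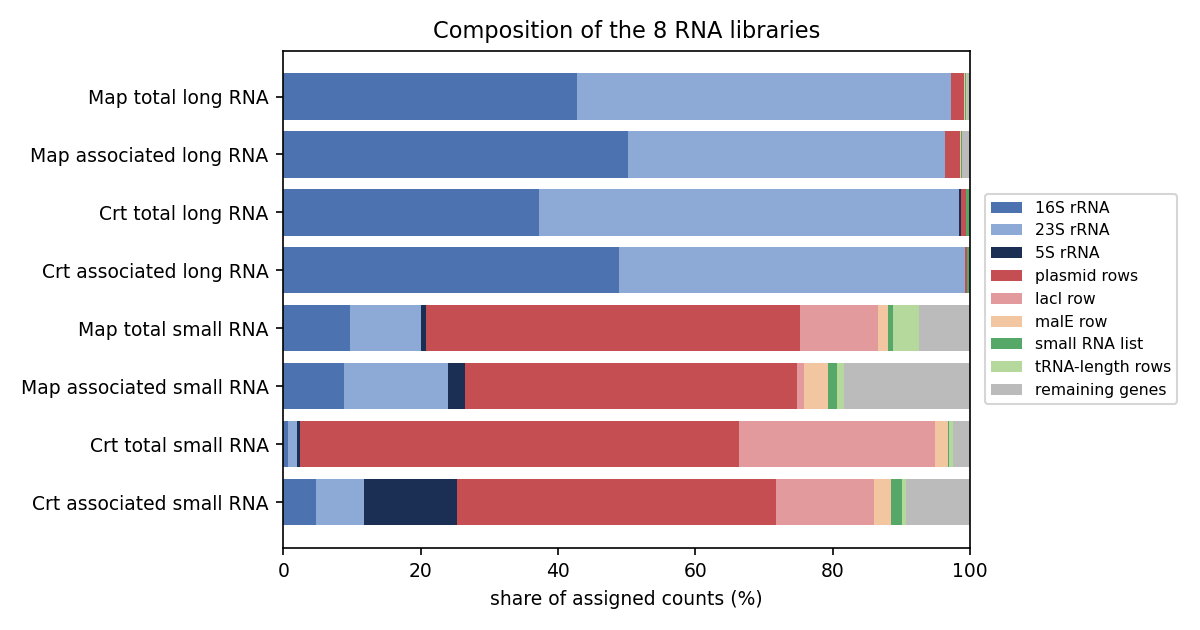
Composition of the 8 RNA libraries. Each bar is 1 library and its segments are the shares (%) of assigned counts in 16S, 23S and 5S rRNA, plasmid rows, the lacI and malE rows, the small RNA list, tRNA-length rows and the remaining genes. Plasmid rows hold between 46.4% and 63.9% of the small RNA libraries, and 5S rRNA reaches 13.5% in Crt associated small RNA.

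The plasmid rows show which vector sequences were found in the material purified with each complex. The row of the complex itself was the largest single row of the Map small RNA libraries, with 34.5% of total and 44.3% of associated counts, a 1.28-fold larger share (1.28 to 1.28), although it was 2.32-fold lower in associated RNA relative to the median gene. With Crt the shares were 24.8% and 27.3%, a 1.10-fold larger share and 2.67-fold lower relative to the median gene. The complex row is also the longest plasmid row. Per kb, the pBR322 origin row held more counts in Map total (1376574 against 991806), Crt total (2596954 against 816805) and Crt associated small RNA (1282010 against 698589). In Map associated small RNA it held fewer (505971 against 2962702). LacI, the repressor gene carried by the plasmid, held 6.50% of Map total and 0.528% of Map associated small RNA, a 12.3-fold smaller share (12.2 to 12.4). With Crt it held 13.5% and 6.58%, a 2.04-fold smaller share. The chromosomal row of the same gene, lacI, held 11.3% and 0.992% with Map, and 28.6% and 14.3% with Crt. KanR, the kanamycin resistance gene, had a 2.46-fold smaller share in associated small RNA with Map and a 2.63-fold smaller share with Crt. For the row named pBR322 origin the share was 6.34-fold smaller with Map and 1.57-fold smaller with Crt, and for the F1 origin 3.20-fold and 2.89-fold smaller. malE, the gene that encodes MBP, held a larger share of associated small RNA, by 2.27-fold with Map and 1.40-fold with Crt, but relative to the median gene it was 1.30-fold and 2.11-fold lower. In Map long RNA, the rows with smaller shares in associated small RNA held larger shares of associated than of total RNA. These were the pBR322 origin (5.29-fold, 5.14 to 5.45), lacI (1.82-fold), LacI (1.75-fold), KanR (1.73-fold) and the F1 origin (1.65-fold). The chromosomal genes outside rRNA, lacI, malE, the small RNA list and tRNA-length rows together held a 2.24-fold larger share there. Of the named rows, only the pBR322 origin exceeded this. Relative to the median gene, lacI was at -0.07 in log2. In Crt long RNA the complex row held a 4.17-fold smaller share (4.13 to 4.21) of associated than of total RNA. Without rRNA in the total, this last difference was 2.20-fold. The pBR322 origin, lacI, LacI, KanR and F1 origin rows also held smaller shares of Crt associated long RNA, from 1.12-fold (lacI) to 1.86-fold (F1 origin). Without rRNA in the total their shares were larger instead, from 1.02-fold (F1 origin) to 1.69-fold (lacI).

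**Figure D2:**
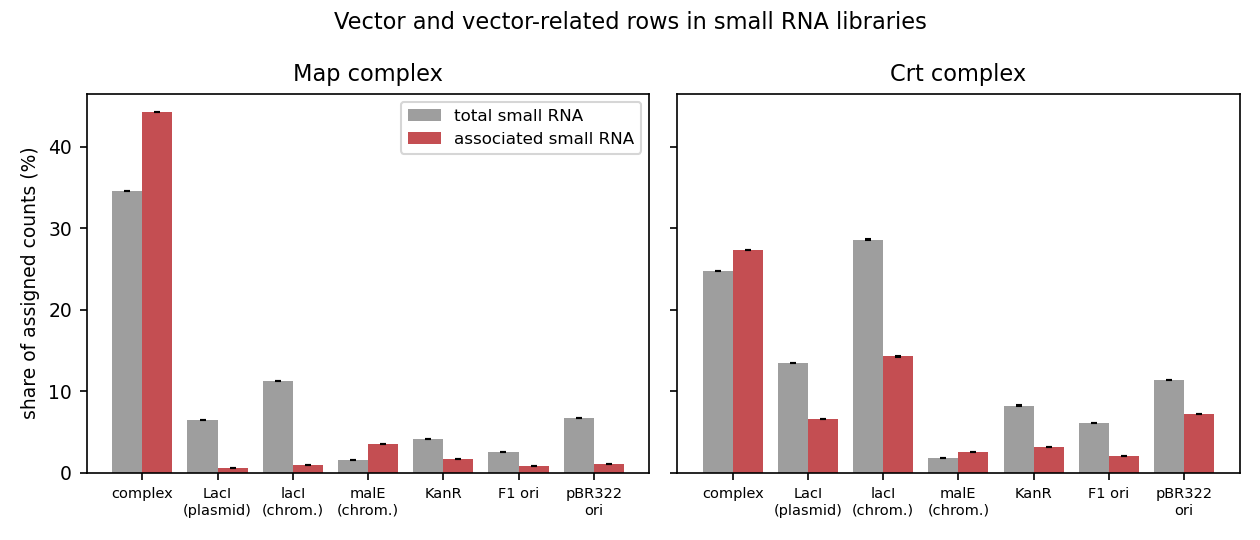
Shares (%) of assigned counts of the complex, the plasmid LacI, KanR and origin rows and the lacI and malE rows in total (grey) and associated (red) small RNA, Map on the left and Crt on the right. Error bars are exact 95% counting intervals and are narrower than the lines. The LacI and lacI shares are smaller in associated RNA with both complexes, from 11.3% to 0.992% for lacI with Map and from 28.6% to 14.3% with Crt.

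The comparison of Map associated with Map total small RNA asks which transcripts give the small RNA that purifies with this complex. Most of the measured housekeeping RNAs were low in the associated library relative to the median gene. 6S RNA (ssrS), which binds RNA polymerase, was 9.29-fold lower than the median gene, and the RNA of the signal recognition particle (ffs) was 11.5-fold lower (11.1 to 11.9). Of the 5 measured small RNAs, 4 were at least 2-fold lower, and only tmRNA (ssrA), which rescues stalled ribosomes, was above the median gene (1.11-fold, 1.10 to 1.12). Their median was -2.74 in log2, at percentile 0.075 of the random lists. As a share of all counts, small RNAs of the list together went the other way, from 0.627% of total to 1.28% of associated small RNA, of which ssrA held 0.361% and 1.19%. Ribosomal protein genes had a median of 0.59 (percentile 100), with 40 of 54 above the median gene, from rpmD at 2.30 (2.08 to 2.53) to rpmH at -2.33 (-2.57 to -2.08). RNA polymerase and nucleoid protein genes had a median of 0.69 (percentile 99.98), with 14 of 21 above the median gene. In this list stpA, a nucleoid protein gene, was 19.3-fold higher (17.2 to 21.7), and crp, the regulator of catabolite repression, was 9.34-fold lower (8.69 to 10.1). Glycolysis genes had a median of 0.61 (percentile 99.96), with 11 of 16 above the median gene and pfkA, a phosphofructokinase gene, at 2.04 (1.73 to 2.37). Flagella and chemotaxis genes had a median of 0.91 (percentile 98.9), with 21 of 25 above the median gene and cheA, the chemotaxis kinase gene, at 3.56 (2.56 to 4.93).

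Among single genes of this comparison, eutP of ethanolamine use (138 against 0 counts) was at least 6.65-fold higher and gadE, an acid resistance regulator (120 against 0), at least 5.78-fold higher. The rhamnulokinase gene rhaB (420 against 1 count) was 47.9-fold higher, with an interval of 10.8 to 2404. Low values were seen at genes of small proteins: mgtS, which acts on magnesium uptake, was 52.1-fold lower (45.8 to 59.8) and pmrR 44.8-fold lower (39.7 to 50.9). The 102 genes under 200 bp had a median of -1.40. The lacI row was 33.8-fold lower. Of 3743 genes, 1097 were at least 4-fold higher and 37 at least 4-fold lower. The median gene lay at 1.36 in log2, and relative to it 270 genes were higher and 183 lower.

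In long RNA, the Map comparison had high values at single genes and low values for cold shock genes. The iscA gene of iron-sulfur cluster assembly (18615 against 26 counts) was 383-fold higher in the associated library (265 to 595). srkA, a stress response kinase gene, was 124-fold higher (71.7 to 258), gpsA of phospholipid synthesis 26.7-fold (17.1 to 46.2) and hns, the nucleoid protein gene, 13.7-fold (12.3 to 15.4). nrfF of nitrite reductase assembly (241 against 0 counts) was at least 43.6-fold higher. The lowest were hemG of heme synthesis, 161-fold lower (96.7 to 329), and speB of putrescine synthesis, 74.4-fold lower (57.7 to 99.9). The 7 measured same-strand neighbours of genes with such 16-fold or larger differences had a median of 0.72 in the direction of those genes, and at most 1.62. All 6 measured cold shock genes were below the median gene, with a median of -1.09 (percentile 0.18). In this list cspG was 7.61-fold lower (6.17 to 9.54) and cspA, an RNA chaperone gene, 5.79-fold lower (5.39 to 6.24). Ribosomal protein genes had a median of -0.45 (percentile 4.80), with 43 of 53 below the median gene. It lay inside the random range, and before centring it ranged from -0.72 to 0.47 with the scaling. For TCA cycle genes the median was -0.58 (percentile 4.71, inside the random range), with 10 of 14 below the median gene, and before centring it ranged from -0.85 to 0.34. With a minimum of 10 counts these 2 medians were -0.80 and -0.93. Of 545 genes, 53 were at least 4-fold higher and 8 lower. The median gene lay at 0.18, and relative to it 40 genes were higher and 11 lower.

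With the Crt complex, housekeeping RNAs were high in the associated small RNA. ffs was 6.54-fold higher than the median gene (6.28 to 6.83), with a share of 0.333% against 0.0172%, and ssrS had a share of 0.967% against 0.0839% and a log2 value of 1.96. All 5 measured small RNAs were above the median gene, with a median of 1.19 at percentile 90.6, inside the range of the random lists. RNA polymerase and nucleoid protein genes had a median of 0.91 (percentile 99.5), with 13 of 20 above the median gene and stpA at 2.18 (2.04 to 2.32). SOS response and recombination genes had a median of 0.62 (percentile 99.2), with 14 of 18 above the median gene and the DNA helicase gene uvrD at 2.03 (1.75 to 2.32). For ribosomal protein genes the median was 0.47 (percentile 98.2), with 35 of 53 above the median gene and rplL at 2.41 (2.30 to 2.53). The gene of a translation initiation factor, infC (31514 against 368 counts), was 37.4-fold higher (33.8 to 41.6), pgi of glycolysis 30.0-fold (23.7 to 39.4) and bamC of outer membrane protein assembly 19.0-fold (16.3 to 22.4). The lowest were nanK of sialic acid use, 94.7-fold lower (69.9 to 134), and araF of arabinose uptake, 21.8-fold lower. nadC of NAD synthesis was 12.1-fold lower. Of 2186 genes, 958 were at least 4-fold higher and 3 lower. Relative to the median gene, at 1.82, 121 were higher and 88 lower.

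In Crt long RNA, 134 genes could be compared. rnpB and ssrA held 51.2% and 13.3% of the counts of the genes used for scaling in the associated library, and 27.5% and 25.9% in the total library. rpoS, the sigma factor gene of the general stress response, was 7.87-fold higher in the associated library (6.20 to 10.2), and fepA, the receptor gene for enterobactin, was 12.9-fold higher. ssb1 (595 against 10 counts) was 132-fold higher (75.1 to 291). corA, a magnesium transporter gene (11 against 7302 counts), was 273-fold lower (159 to 569), and nuoC of NADH dehydrogenase was 55.3-fold lower (33.9 to 105). ffs, with 0 against 146 counts, was at least 20.8-fold lower, and cspA was 6.71-fold lower. Ribosomal protein genes had a median of -0.19 (percentile 2.35, on the lower edge of the random range), with 29 of 42 below the median gene and rplJ 3.35-fold lower (2.79 to 4.06). With a minimum of 10 counts this median was -1.63. The folds of this comparison depend on that minimum, since with 10 counts the median gene moved from -0.95 to 0.41, and relative to it rpoS was 3.08-fold and fepA 5.06-fold higher. There were 8 genes at least 4-fold higher and 12 lower. Relative to the median gene, 11 were higher and 7 lower.

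The total RNA of cells with the Map complex was set against that of cells with the Crt complex, to show how the RNA pools of the expressing cells differed. TCA cycle and heat shock genes were higher in Map cells in both RNA fractions. The libraries also differed in stable RNA: in total small RNA, 16S, 23S and 5S rRNA together held 20.7% with Map and 2.42% with Crt, and tRNA-length rows held a 6.43-fold larger share with Map. In total long RNA, 5S rRNA held a 96.2-fold smaller share with Map. In long RNA, TCA cycle genes had a median of 1.70 (percentile 100), with 9 of 10 above the median gene. sucA, a subunit gene of oxoglutarate dehydrogenase, was at 2.39 (2.03 to 2.79), and mdh of malate dehydrogenase was lowest at -1.19 (-1.53 to -0.86). Heat shock and protein quality control genes had a median of 1.36 (percentile 99.96), with 10 of 11 above the median gene. hslU, a protease subunit gene, was at 2.26 (1.60 to 3.08), and clpA, another, at -1.26 (-1.59 to -0.93). Ribosomal protein genes had a median of -0.30 (percentile 7.91), with 47 of 51 below the median gene, and before centring this median ranged from -0.18 to 0.73 with the scaling. In small RNA, all 16 TCA cycle genes were above the median gene (median 1.75, percentile 99.98), and sucD, a succinyl-CoA synthetase gene, was 274-fold higher (168 to 539). Heat shock genes had a median of 1.41 (percentile 99.98), with 15 of 19 above the median gene, from ibpB, a small chaperone gene, at 4.51 (3.52 to 6.11) to the protease gene lon at -0.58 (-1.02 to -0.11). Ribosomal protein genes had a median of 0.44 in small RNA (percentile 98.1).

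Single genes with large differences in total long RNA were speB (141-fold higher in Map cells, 72.9 to 374) and corA (1268-fold lower, 756 to 2560). The arabinose transporter gene araE (2 against 139 counts) was 120-fold lower, with an interval of 41.0 to 1259. In total small RNA, zapA of cell division was 236-fold higher (192 to 297), and nanK was 31.7-fold lower. Of 267 genes in long RNA, 49 were at least 4-fold higher in Map cells and 12 lower. Relative to the median gene, at 1.03, 14 were higher and 19 lower. Of 2069 genes in small RNA, 1060 were higher and 10 lower. The median gene lay at 2.04, and relative to it 163 were higher and 143 lower.

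The associated RNA of both complexes was compared directly as well. In small RNA, 3 of the 5 small RNAs were at least 2-fold lower with Map and 2 at least 2-fold higher, with a median of -2.38 (percentile 0.495). ssrS was lowest, 48.6-fold lower (47.7 to 49.5), while rprA, a regulator of rpoS translation, was at 1.14 (0.98 to 1.30) and ssrA at 1.06. TCA cycle genes were higher with Map (median 1.48, percentile 100, 14 of 16 above the median gene), led by sucC, a succinyl-CoA synthetase gene, at 3.26 (2.99 to 3.55). Heat shock genes had a median of 0.87 (percentile 99.8), with 19 of 20 above the median gene and hslV at 2.90 (2.68 to 3.12). Ribosomal protein genes had a median of 1.02 (percentile 100), with 47 of 54 above the median gene and rplJ 8.78-fold higher. pflA, which activates pyruvate formate lyase, was 51.4-fold higher with Map (43.4 to 61.6), and infC 14.2-fold lower (13.9 to 14.5). In long RNA, TCA cycle genes had a median of 0.83 (percentile 99.1, 11 of 12 above the median gene) and heat shock genes 0.60 (percentile 98.3, 11 of 14), with the chaperone gene dnaK at 1.60 (1.30 to 1.91). Both lists were also higher in the total RNA of Map cells, so these values do not show a preference of the Map complex for them. In associated over total small RNA, the TCA cycle median before centring ranged with the scaling from -0.59 to 0.99 with Map. With Crt this range was 0.12 to 2.38. iscA was 141-fold higher with Map (91.1 to 243), and the RNase P RNA (rnpB), which processes tRNA precursors, 63.6-fold lower (62.1 to 65.2). With a minimum of 10 counts the median gene of this comparison lay at 0.86, and relative to it iscA was 267-fold higher and rnpB 33.7-fold lower. Of 3792 genes in small RNA, 768 were at least 4-fold higher with Map and 59 lower. Relative to the median gene, at 1.29, 99 were higher and 184 lower. Of 431 genes in long RNA, 182 were higher and 10 lower. The median gene lay at 1.78, and relative to it 31 were higher and 29 lower.

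**Figure D3:**
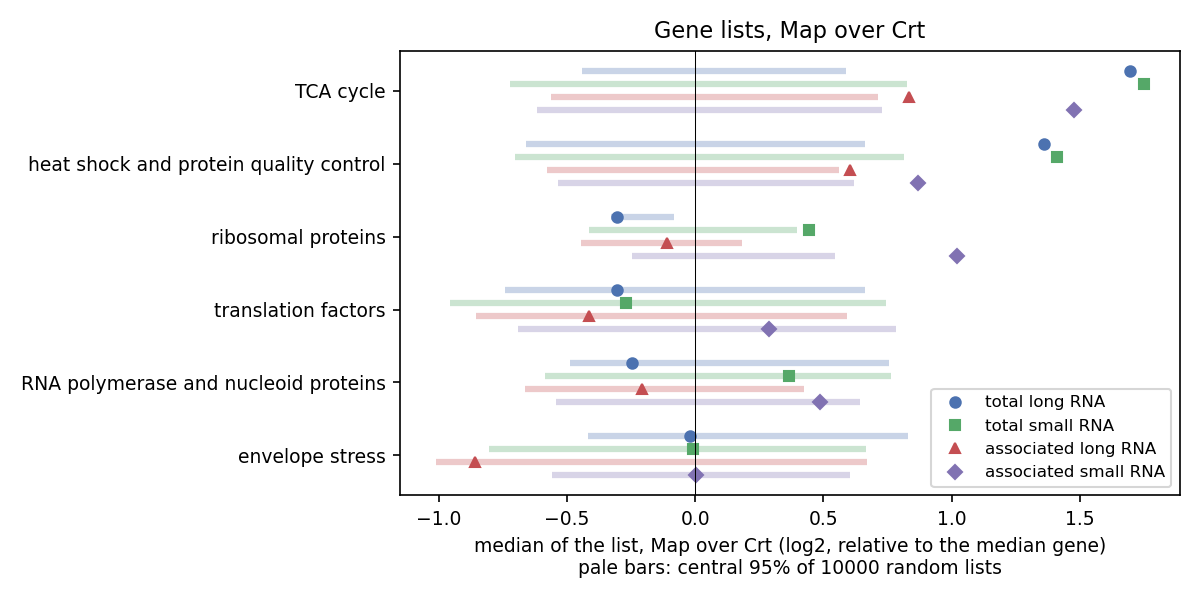
Medians of 6 gene lists in Map over Crt libraries (log2, relative to the median gene), 1 symbol per RNA fraction. Pale bars are the central 95% of 10000 random lists matched for size and expression. TCA cycle medians lie between 0.83 and 1.75 and heat shock medians between 0.60 and 1.41, all above their random range.

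Whether the same genes were over-represented with both complexes was asked by a correlation across genes, which are not independent replicates. For small RNA, the associated-over-total log2 ratios of Map and Crt had a Pearson r of 0.34 across 2170 genes (Spearman rho 0.35). Genes high with both included stpA (4.27 and 2.18), and genes low with both included cspD, an inhibitor of replication (-3.88 and -3.77), while ssrS and ffs had opposite signs. For long RNA r was 0.34 across 121 genes (rho 0.37). Small and long RNA ratios within a complex had an r of 0.02 across 544 genes for Map (rho -0.02) and of 0.04 across 131 genes for Crt (rho 0.09). These are 4 correlations in all. With at least 1000 counts per gene, the long RNA correlation between complexes rested on 9 genes and had the opposite sign.

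**Figure D4:**
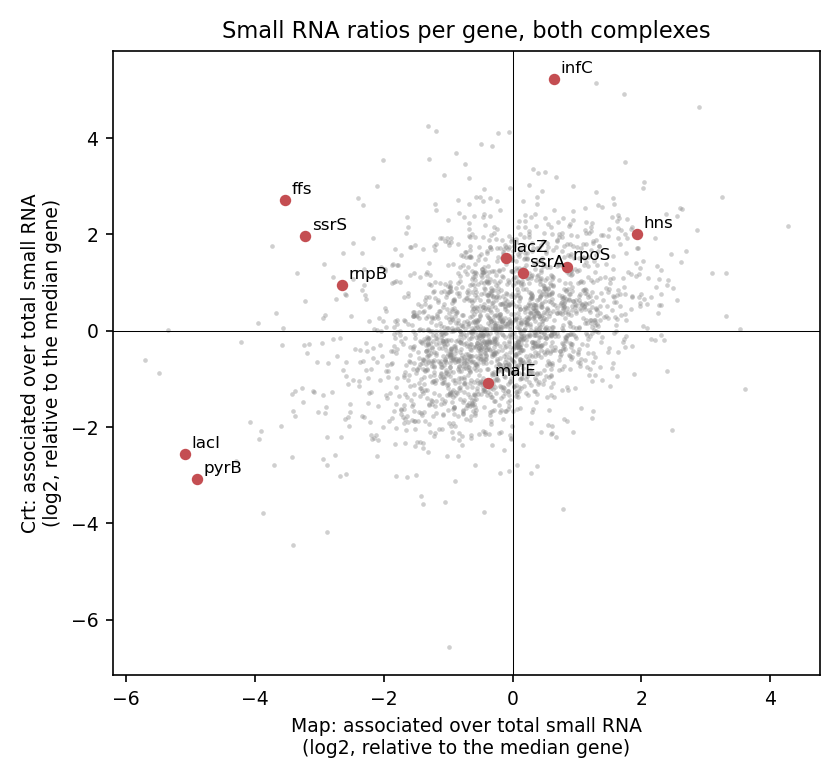
Associated over total small RNA per gene (log2, relative to the median gene), Map on the x axis and Crt on the y axis, for 2170 genes with at least 100 counts in each comparison. The labelled genes were partly chosen after their values were seen. 6S RNA (ssrS) and the signal recognition particle RNA (ffs) lie low with Map (-3.22 and -3.53) and high with Crt (1.96 and 2.71).

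The DNA that purified with the Map complex gave few counts: the authors' overview lists 883 of 308789 reads as aligned (0.286%). Of 4169 rows, 524 had a count and none reached 100 counts, so that no gene could be ranked by density. The rows with at least 10 counts were lacI (22), the complex (14), the pBR322 origin (12), bamA of outer membrane assembly (11) and LacI (11), named after their values were seen. Plasmid rows held 45 counts, a share of 5.03% (3.69% to 6.68%). They had 6.31 counts per kb, against 0.197 per kb for chromosomal rows without rRNA, lacI and malE, a 32.1-fold higher density (23.2 to 43.4). No input DNA was used here, and the copy number of the plasmid is part of this ratio. Genes in the part of the chromosome nearer to dnaA, the replication initiator gene close to the origin, had 1.15 times the density of those farther away, with an interval that includes 1 (0.995 to 1.33).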

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

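Of the tests in this part, only the one on neighbouring genes was set before its result was seen. The tests of counting error, of tRNA-length rows, of the direct comparison of associated libraries and of exchanged libraries were chosen after the counts had been seen, and the bound of the tRNA-length test was rewritten after its value was known. Under its first bounds that test was undecided. Values relative to a median gene over genes with at least 10 counts were added after the results were seen.

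Some housekeeping RNAs lay at least 2-fold from the median gene on opposite sides with the Map and the Crt complex. In small RNA these were 2 of the 5 measured: ssrS (6S RNA) had an associated-over-total log2 value of -3.22 with Map and 1.96 with Crt, and ffs (signal recognition particle RNA) had -3.53 and 2.71. In long RNA, rnpB (RNase P RNA) had -2.13 and 1.84, but relative to a median gene over genes with at least 10 counts these were -2.48 and 0.49, and the Crt value was then below 2-fold. The others did not lie 2-fold away on both sides. In small RNA, however, 4 of the 5 lay at least 2-fold below the median gene with Map, and all 5 lay above it with Crt. Only ssrA lay above it with both complexes (0.15 and 1.19). In long RNA, ssrS lay below the median gene with both (-2.49 and -1.02). The long RNA libraries did not repeat the small RNA pattern: with Crt, ffs was at least 20.8-fold lower in associated than in total long RNA (0 against 146 counts). By share, 5S rRNA was 96.2-fold lower in Map than in Crt total long RNA and 12.4-fold lower in associated long RNA. With 1 library per group the difference between the complexes was not tested.

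For 5S rRNA, ssrS and ffs in small RNA, 3 technical explanations were set against the values. If only the Crt total library were poor in them, the associated libraries compared directly would be alike, but by shares of all counts the 3 RNAs had a median log2 ratio of 4.19 (lowest 2.5046, highest 4.51) in Crt over Map. If the Crt library had kept more of all short stable RNA, the tRNA-length rows would share this difference, but the median of 83 such rows was 0.60 (-0.08 to 1.05, bootstrap), which could account for part of it at most, and their summed share was 1.83-fold higher with Map. If the associated libraries of the 2 complexes had been exchanged, and each table was counted against its own complex, their reads would match the complex row poorly, but that row held at least 10.7 times the malE counts in each of the 4 associated libraries. An exchange of the libraries together with the complex they were counted against is not covered by this. The descriptions of the associated samples name the other complex than their titles, and a summary label for Crt names the Map complex. Also open is a difference in the size range or the handling of these single libraries, which the values for 5S rRNA and ffs in long RNA leave possible. A difference between the complexes in the RNA they carry stays open too and was not tested.

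Single genes with ratios of 16-fold or more between long RNA libraries, such as iscA and corA, formed the other pattern that was weighed. The counting intervals decide nothing here: 100% of the 42 gene and comparison pairs stayed at 4-fold or more at the nearer end, but the choice of pairs by ratio and count all but fixes this. A local fragment in place of a whole transcript may be the source: neighbours on the same strand within 100 bp had a median log2 ratio of -0.22 (-0.57 to 0.33) in the direction of the extreme gene, or 0.12 (-0.25 to 0.37) with the median gene taken over genes with at least 10 counts. By comparison this median was 0.72 (Map associated against total, 7 values), -1.64 (Crt, 1 value), -0.97 (total, 5 values) and -0.48 (associated, 8 values), so that in the first some neighbours moved part of the way. The test rests on 21 neighbour values, some of them from the same gene in several comparisons, and adjacent genes need not share a transcript.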

How the results depend on the processing

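No paired analysis was run. Each comparison has 1 library on either side and comes from no test. Over the 2 complexes, associated and total libraries form 2 pairs in each RNA fraction, and a change shared by both pairs was not tested. Leaving out a DNA replicate was not possible because both samples share a column. The alternatives without lacI and malE in the library size, and median of ratios between the complexes, were added after the data were seen. Counts of genes at least 4-fold higher or lower (before centring) moved with the scaling and the count minimum. The scaling shifts all genes of a comparison alike, and a count minimum changes which genes are compared; other causes were not tested. Apart from the list medians, 50 alternative values stayed within their limits, 67 moved and 1 turned its sign. The limits were a fixed fold for counts of genes, and bootstrap or counting intervals for other values. For plasmid shares of RNA libraries the counting interval is so narrow that leaving out rRNA all but fixes a move. The label of DNA rows at a minimum of 10 was set in advance. This tally is therefore no measure of robustness. Of the list medians, 108 stayed and 6 moved, all 6 in long RNA at a minimum of 10 counts. At that minimum the median gene of Crt associated against total long RNA changed sign, from -0.95 to 0.41, and that of associated long RNA between the complexes went from 1.78 to 0.86, so that all values relative to it shift. Named genes relative to this median were added after the data were seen.

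In associated against total small RNA with Map (1097 higher, 37 lower), TMM gave 293 higher and 174 lower, median of ratios 273 and 184, no lacI and malE 367 and 131, and a minimum of 1000 counts 240 and 13. With Crt (958 and 3), TMM gave 85 and 127, median of ratios 82 and 143, no lacI and malE 59 and 188. A minimum of 10 gave 2109 higher, a minimum of 1000 gave 118 higher, and all assigned counts gave 8 lower. In long RNA with Map (53 and 8), TMM and median of ratios both gave 32 higher, thinning 35 higher, all assigned counts 93 and 4, a minimum of 10 304 and 15, and a minimum of 1000 6 and 3. With Crt (8 and 12), TMM gave 37 lower, median of ratios 38 lower, all assigned counts 20 lower, a minimum of 10 288 and 43, and a minimum of 1000 0 and 4.

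For Map against Crt, TMM gave 20 higher in total long RNA (49), 179 higher and 119 lower in total small RNA (1060 and 10), 99 higher in associated long RNA (182), and 105 and 180 in associated small RNA (768 and 59). Median of ratios gave 17 higher, 178 and 120, 97 higher, and 104 and 182 in the same order. A minimum of 10 gave 297 and 36 in total long, 1789 and 23 in total small, and 497 and 101 in associated long RNA. Thinning gave 109 higher in associated long RNA.

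The correlation of both complexes in small RNA was 0.41 at a minimum of 10 (0.34 in the report) and 0.29 at 1000. In long RNA it was -0.23 at a minimum of 1000, where 9 genes were left. Without rRNA in the total, plasmid rows held 68.7% of Map total long, 60.0% of Map associated long, 68.8% of Map total small, 65.7% of Map associated small, 56.0% of Crt total long, 29.2% of Crt associated long, 65.4% of Crt total small and 62.1% of Crt associated small RNA. In DNA, 5 rows passed a minimum of 10 counts and 0 one of 100. Depth limits the long RNA comparisons, with 134 genes compared for Crt, and the DNA column most.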

Other observations

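Of the tests in this part, the one on gene length was chosen after the result was seen. Those on malE, on associated small RNA and on DNA were set before. Named genes were in part chosen after their values were seen.

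Further gene groups differed between the associated small RNA of both complexes. Flagella and chemotaxis genes were higher with Map (median 0.55, percentile 99.6, 20 of 25 above the median gene), with flgF of the flagellar rod at 1.69 (0.77 to 2.88). They were higher in total small RNA of Map cells too, with a median of 2.65 before centring and the median gene at 2.04. In associated over total small RNA, their median before centring ranged with the scaling from 0.90 to 2.48 with Map and from 0.68 to 2.94 with Crt. Cold shock genes had a median of 0.87 (percentile 98.0, 7 of 9), with cspG at 3.63 (3.26 to 4.04) and cspH lowest at -2.92 (-3.49 to -2.39). ATP synthase genes had a median of 0.76 (percentile 96.5, inside the random range), with 8 of 9 above the median gene. Iron acquisition genes showed no common direction (median 0.14, percentile 78.9), but entF, of enterobactin synthesis, was 34.7-fold lower with Map (32.5 to 37.1) and was 15.7-fold lower (13.1 to 19.0) in total small RNA too. Of the 21 lists measured in this comparison, 5 lay above and 1 below the range of the random lists.

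In small RNA, the associated-over-total values of lacZ (beta-galactosidase) and lacY (lactose permease) differed between the complexes. Direct values between the associated libraries are not given here for these genes. The lac list also holds the lacI row, which stands for 2 loci and is not read as the chromosomal gene alone. With Map, all 4 rows of the list (lacZ, lacY, lacA and lacI) were below the median gene. lacY was 6.93-fold lower (6.24 to 7.71) in associated than in total small RNA, while lacZ was at -0.10 (-0.18 to -0.03). With Crt, 2 rows were above and 2 below the median gene, with lacI included in this count. There lacZ was at 1.51 (1.36 to 1.67) and lacY at -0.18 (-0.61 to 0.28). In total small RNA, lacY was 4.74-fold and lacA 5.38-fold higher in Map than in Crt cells. Toxin and restriction genes in Map small RNA had a median of -0.61 (percentile 3.83, inside the random range), and hokB, a membrane toxin gene, was 7.71-fold lower (7.03 to 8.47). This list's sign before centring depended on the scaling.

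Reads of the vector tag may fill the malE row: malE had at least 421 times the reads per kilobase of the median of the 13 other maltose genes in each of the 8 RNA libraries, and up to 15226 times.

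Small RNA associated with a complex might follow the abundance of long transcripts. Across genes, which are not independent replicates, associated small RNA had a rank correlation with total long RNA of 0.75 with Map, against 0.73 for total small RNA, a difference of 0.0246 (0.00181 to 0.0489). With Crt the correlations were 0.63 and 0.58, a difference of 0.0516 (0.0128 to 0.0921). The Map difference lies between the bounds set for and against, so this stays open.

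Gene length could set part of the ratio of associated to total small RNA. The rank correlation of the ratio with length was 0.26 with Map and 0.12 with Crt, between the bounds. Genes under 200 bp had a median of -1.40 with Map (-1.64 to -0.91, 102 genes) and of 0.20 with Crt (-0.54 to 0.66, 58 genes).

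DNA counts per gene followed gene length more closely than total long RNA: their rank correlation with Map total long RNA was 0.07 across 4097 genes and that with gene length 0.23, a difference of -0.16. The correlation with Map associated small RNA was 0.18, close to that with gene length, so a relation with associated small RNA stays open.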
